A study of Mus musculus with 4 samples.

How the data were processed

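Gene expression was measured on 4 single-colour microarrays, each hybridised with Cy3-labelled cRNA from mouse CD4+ T cells. Per the labels, the cells came from NFS/sld mice with or without removal of the thymus, which in this strain leads to a disease resembling Sjögren's syndrome. The 4 samples combine surgery (thymectomy, TX, or none, nonTX) with the sorted fraction (CD25+ or CD25−). Each sample is RNA pooled from 4 mice, 150 ng of which was labelled, and each group has 1 array. Pooling averages over animals but leaves no replicate array, so the spread between mice is not measured here.

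The deposited scanner files hold spot brightness as intensity on a linear scale. Per the submitters' processing notes, the images were read with Agilent Feature Extraction version 10.7.1.1. Per the file headers, its processed signal has the background already removed. The same deposited files carry 0 or 1 flags for each spot, in columns of another kind than a measurement, which state whether a spot is a control, lies well above background, is saturated or is an outlier. The authors also deposited a table of log2 values for the same arrays. Setting differences between its columns against differences between the scanner values showed that it holds log2 processed signal, shifted by 1 constant per array and centred on each probe's median over the 4 arrays. For every pair of arrays at least 99.9975% of the probes matched within 0.001 on the log2 scale, after the constant was removed. The direction and the scale are therefore settled, and the origin of the constants is not given in the sources used here. The medians of its columns were 0.15 for nonTX CD25+, −0.09 for TX CD25+, 0.01 for nonTX CD25− and −0.03 for TX CD25−.

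The scanner file of the nonTX CD25+ array was held here only in part, with 24535 complete spots (55.3%). For 17783 of the 39429 non-control probes at least 1 spot was missing, and their value on that array was recovered from the authors' log2 table. Probes with all spots held matched that table within 3e-06 on the log2 scale. For the 17384 probes with no spot held, a processed signal of at least 18.2 was taken as well above background. That rule gave the scanner's own flag for 98.8% of the held spots. Rules set the same way on the first part of each complete array gave the scanner's flag for 98.9% to 99.3% of the spots in its second part.

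Control spots and spots marked as outliers were left out, and spots of 1 probe were averaged on the log2 scale. Each array's 75th percentile of log2 processed signal was subtracted. A level below is this difference, and levels are compared only between arrays for the same probe. A gene with several probes was represented by the brightest. Symbols came from a RefSeq gene table of assembly GRCm38.p6, matched on the accession of each probe without its version. A symbol was found for 26575 probes (67.4%), which stand for 20140 symbols. The array annotation uses an older build, so no coordinates are given. The 12854 other probes are counted under the name the files give them and are not named, and the analysis ran on 32571 genes or unnamed transcripts, called features below.

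A ratio was computed where the gene lay well above background on at least 1 of the 2 arrays. Where it did so on 1 array only, the dimmer value was raised to the lowest signal of any probe well above background on that array if it lay under it, and the ratio is a bound, printed as "at least". A bound that would have pointed the other way was set to no change. A feature was counted as higher or lower at a ratio of 2-fold or more. With 1 array per group there is no p-value for these ratios, and they describe these arrays and pools. Technical spread was taken from 2 sources. Probes with at least 4 spots had a median SD of 0.05 to 0.08 on the log2 scale within an array. Different probes of a gene had a median SD of 0.12 to 0.23 in their log2 ratio, and a pooled SD of 0.32 to 0.41. All 4 arrays lay on 1 slide and were scanned together, and each group has its own array, so a difference between groups cannot be told apart from a difference between arrays.

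Before the data were examined, 33 gene lists were written down, covering T helper classes, T cell states and other cell types that a spleen sort might hold. For each list and comparison with at least 3 measured members, the median log2 ratio was given its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A list outside the central 95% is said to stand apart. This is a description of the arrays and not a p-value. On simulated ratios for TX over nonTX in CD25−, 198 of 200 changed genes among 18713 passed 2-fold, as did 21 unchanged ones, at a noise SD of 0.3. All planted changes were larger than 2-fold, so most passed by construction. Of 200 unchanged lists 4.5% stood apart. Their genes had independent noise, so a share of about this size was fixed beforehand. It is not an error rate for lists whose genes move together.

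A linear model with a fraction and a surgery term was fitted to the 20084 features well above background on at least 2 of the 4 arrays, with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 and Benjamini-Hochberg adjustment at 0.05. It takes the difference between the 2 surgery ratios as error and has 1 residual degree of freedom. On simulated arrays for the surgery effect, with 20084 features, it called 0% of the genes changed by 2-fold, 0% of those changed by 4-fold and 0% of those changed by 8-fold. The simulation changed 66 or 67 genes at each fold, and what the model recovers depends on that share. A count of 0 from this model therefore does not show that no gene differs. Other steps used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

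The genes named in the text were chosen by a rule written before the data were examined. It takes Ascl2, Foxp3, Il2ra and Cd4, then the highest and lowest measured ratios of each comparison, 10 each way for TX over nonTX in CD25−, 8 for TX over nonTX in CD25+ and for CD25+ over CD25− in nonTX, and 5 for CD25+ over CD25− in TX. It adds the largest bounds of each comparison, the 5 largest differences each way between the 2 surgery ratios, and from each list the members at 2-fold or more, or a few with the largest ratios. Predicted genes and clone names were skipped, and some genes are not reported here. Outside this rule, and chosen after their values were seen, are Cxcr5, Pdcd1, Maf, Bcl6, Icos, Il17a, Mki67, Cdkn2a, Il10, Cd3e, Ccr4 and Ccr8 in CD25− cells, Il4, Bcl6, Cd79a and Cd79b in CD25+ cells, and Klrg1 in the nonTX pair. The values of Ascl2, Il2ra and Cd4 on the nonTX CD25+ array were among those recovered from the log2 table. Alternatives planned beforehand covered quantile normalization, scaling on the median of probes well above background on all 4 arrays, normexp background correction with an offset of 50 on spot medians, the authors' log2 table, the mean over probes, a stricter and an absent filter on dim probes, outlier spots kept, a 3-fold threshold, an intensity trend in the linear model, random lists not matched on expression, and lists without shared members. Added after seeing the data were an analysis of the held spots alone and scaling on the E1A spike-in controls.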

Results

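The 4 arrays described CD4+ T cells of NFS/sld mice, split by CD25, the alpha chain of the interleukin 2 receptor that marks most regulatory T cells, with or without thymectomy. By its title the study is about follicular helper T cells (Tfh, the class that helps B cells in germinal centres) and Ascl2, a transcription factor known to promote them. Its stated comparison is TX against nonTX in CD25− cells. The labels name spleen as the tissue in one field and the mouse ear in the extraction text. Ratios between arrays cannot tell which tissue was used.

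The 75th percentile of the processed signal was 766 on the nonTX CD25+ array, 1051 on TX CD25+, 900 on nonTX CD25− and 1009 on TX CD25−. Between 59.1% and 62.8% of the features lay well above background, and no non-control spot among those held was saturated. The scanner's median CV over replicate spots was highest, at 6.13%, on the nonTX CD25+ array and 3.18% to 4.10% on the others. Pearson correlations between arrays across the 18068 features well above background on all 4 ranged from 0.960 to 0.984.

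The sort labels were checked first. Foxp3, the lineage factor of regulatory T cells, was 18.0-fold higher in CD25+ than in CD25− cells without surgery and 15.7-fold higher after it. Il2ra, which encodes CD25, was 15.8-fold and 21.7-fold higher. Cd4 had levels between 4.11 and 4.68 on the 4 arrays. The transcripts of the Y-linked genes tested were not well above background on any array, and Xist was.

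**Figure D1:**
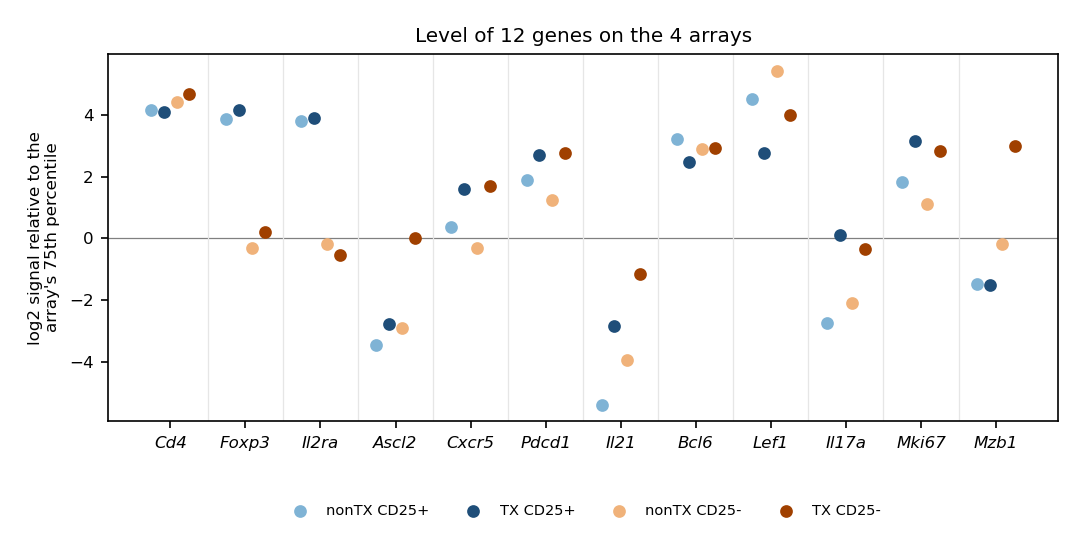
Levels of 12 genes on the 4 arrays (y axis, log2 signal relative to the array's 75th percentile, 1 point per array and no replicates, to be compared within a gene). Foxp3 and Il2ra lay higher on both CD25+ arrays, and Ascl2 was at 0.03 on the TX CD25− array against −2.90 on nonTX CD25−.

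In CD25− cells, Ascl2 was 7.58-fold higher after thymectomy, with a level of −2.90 without and 0.03 with surgery. Of the Tfh list, 11 of 24 measured members were at least 2-fold higher and 0 lower (median log2 ratio 0.96, percentile 100). Il21, the cytokine by which Tfh cells act on B cells, had a log2 ratio of 2.81, Cxcr5, the receptor that draws them into follicles, 2.0, Pdcd1, which encodes PD-1, 1.53, and Maf 1.21. Cebpa at 2.78 and Pou2af1 at 2.07 were also among the 11. The level of Pou2af1 was −0.13 on nonTX CD25− and 1.94 on TX CD25−, and lower on both CD25+ arrays (−1.53 and −1.10). Bcl6, the master factor of the class, stood at 0.05, and Icos at 0.54. The B cell and plasma cell lists had higher medians on this array pair, 1.87 and 2.35. The erythroid and macrophage lists also reached percentile 100 on it. Over the 4 comparisons 86 of 124 list medians stood apart, so percentile 100 does not single out the Tfh list. Ascl2 was measured by 1 probe.

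**Figure D2:**
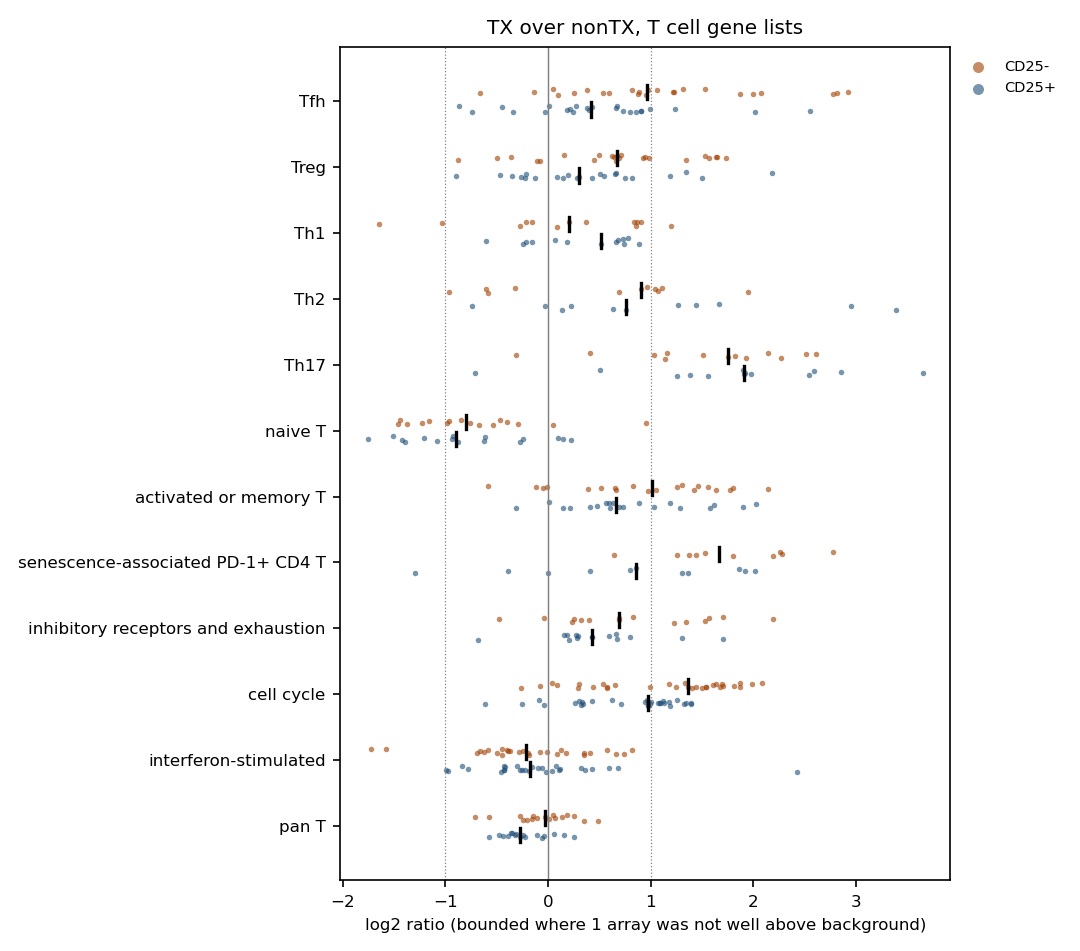
Log2 ratio of TX over nonTX (x axis) for the measured members of 12 T cell gene lists (y axis), with CD25− in brown and CD25+ in blue, 1 point per gene and a black bar at the list median. Dotted lines mark 2-fold, and the Th17 medians of 1.75 and 1.91 lie beyond it while the naive T medians are −0.80 and −0.90.

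Other T helper and activation genes were also higher in CD25− cells after surgery. In the Th17 list 11 of 13 members were at least 2-fold higher (median 1.75, percentile 100), among them Il1r1 with a log2 ratio of 2.51, Ccr6 with 2.14, and Il17a with 1.75. Of the activated or memory list 10 of 20 were higher (median 1.01), led by S100a4 at 2.15 and S100a6 at 1.80. Of the cell cycle list 19 of 31 were higher and 0 lower (median 1.36), with Ccna2 at 2.08, Ccnb1 at 1.98 and Mki67 at 1.70. The list of senescence-associated PD-1+ CD4+ T cells, an aged subset described in autoimmunity, had 9 of 10 members higher (median 1.67), including Cebpa at 2.78, Penk at 2.28, Sostdc1 at 2.26 and Cdkn2a, which encodes the cell cycle inhibitors p16 and p19, at 1.80. Among inhibitory receptors 6 of 15 were higher (median 0.69), with Lag3 at 2.19 and Havcr2 at 1.71. Without the 9 members that other lists share, this list no longer stood apart (median 0.28, percentile 92.0). The Th2 list had 4 of 11 members higher (median 0.90), led by Il1rl1 at 1.95, and the Treg list 6 of 23 (median 0.67), with Il10 at 1.53 and Plagl1 at 1.73, whose 4 probes disagreed (−0.31 to 1.86). Of the 23 Treg list members 18 lay above 0 and 5 below, with Foxp3 at 0.50 and Il2ra at −0.36. The Th1 list did not stand apart (median 0.20, percentile 96.9) except with normexp (percentile 98.9), with Ifng at 1.19 and Txk at −1.64.

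Genes of naive T cells were lower. In that list 5 of 16 members were at least 2-fold lower and 0 higher (median −0.80, percentile 0.00). Dapl1 had a log2 ratio of −1.46, Lef1 −1.44, Satb1 −1.37 and Il7r, the interleukin 7 receptor, −1.16. The pan T list had 0 of 17 members past 2-fold and stood apart (median −0.03 at percentile 99.1, but 0.13 after quantile normalization, and not standing apart on the held spots alone or against random lists not matched on expression), with Cd3e at 0.05. Interferon-stimulated genes did not stand apart (median −0.22, percentile 13.7). Of 23 immediate early and T cell receptor-induced genes 7 were higher (median 0.24, percentile 99.99), with Ier3 at 2.41 and Fos at 1.98, but on the held spots alone the list did not stand apart (median 0.067, percentile 94.1). The list of recent thymic emigrants did not stand apart (median 0.10, percentile 92.8).

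Markers of other cells were higher on the TX CD25− array too. Of the B cell list 14 of 18 members were at least 2-fold higher (median 1.87), with Vpreb3 at 2.77 and Cd79b at 2.67. Of the plasma cell list 6 of 8 were higher (median 2.35), with Tnfrsf17, which encodes the survival receptor BCMA, at 3.31, Mzb1 at 3.19 and Derl3 at 3.01. Monocyte and macrophage genes were higher for 17 of 19 members (median 1.91), erythroid genes for 11 of 12 (median 2.19), basophil and mast cell genes for 6 of 6 (median 2.48), and dendritic cell genes for 7 of 11 (median 1.20). Platelet genes were higher for 5 of 10 (median 0.87), neutrophil genes for 2 of 8 (median 0.67) and NK genes for 3 of 9 with 1 lower (median 0.66). The NK list did not stand apart on genes well above background on all 4 arrays (median 0.14), with the mean over probes (median 0.48) or on the held spots alone (median −0.48). Stromal and endothelial genes were higher for 3 of 10 (median 0.57), but the list did not stand apart on genes well above background on all 4 arrays (median 0.17), with no filter (median 0.23) or with normexp (median 0.18). The keratinocyte list did not stand apart here (median 0.01) or between any other pair of arrays compared. Both measured CD8 genes were below 0, with Cd8b1 at −0.82. These values stand beside every gene group of this comparison.

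Over all features, 1963 of 20820 were at least 2-fold higher and 1072 lower in CD25− cells after surgery, 1479 and 576 of them genes with a symbol. The highest measured ratio was that of Slpi, an inhibitor of leukocyte proteases, at 21.8-fold. It was followed by Tnfrsf17 at 9.91-fold, Insl5 at 9.41-fold, Mzb1 at 9.15-fold, Tomt at 9.10-fold, Gdf15, a stress-induced cytokine, at 8.88-fold, Ecel1 at 8.68-fold, Oosp1 at 8.56-fold, Krt17 at 8.30-fold and Derl3 at 8.07-fold. Among the lowest were Dmbt1 at 7.04-fold lower, Smarcd3 at 6.98-fold, Ankrd34b at 6.88-fold and Bbs10 at 6.57-fold lower, then Sprr1a, Fgfr4, Ly75, Cplx2 and Vash1 with log2 ratios from −2.68 to −2.57. The probes of Cplx2 disagreed, with log2 ratios between −3.81 and 1.68 over 4 probes, as did those of Vash1 (−2.57 to 0.07) and Bbs10 (−2.72 to −0.11). Among genes well above background on 1 array only, Cibar2, Prr33, Mcpt4, a mast cell protease, Pou4f3 and Misp were at least 15.6-fold to 17.8-fold higher. Aqp9, Efcc1, Olfr1286, Krtap15 and Ly6h were at least 11.6-fold to 17.9-fold lower. Several of the measured ratios rest on dim signal. Tomt, Ecel1, Krt17 and Gdf15 lay at −5.96 to −5.23 on nonTX CD25−, where the lowest signal well above background was −6.10. Smarcd3, Ankrd34b and Sprr1a lay at −5.90 to −5.69 on TX CD25−, where it was −6.03. With normexp background correction the counts were 968 higher and 406 lower. The median log2 ratio of features measured on both arrays was −0.12, while the ratios are relative to each array's 75th percentile.

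**Figure D3:**
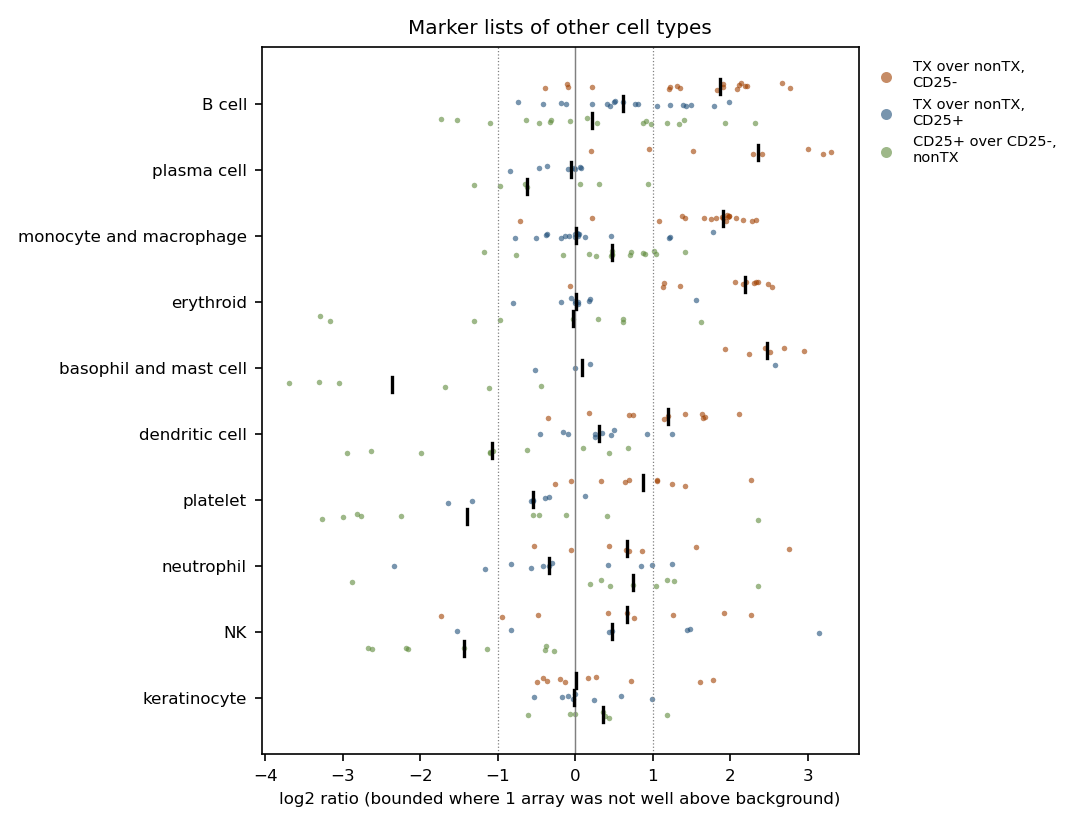
Log2 ratio (x axis) of the measured members of 10 marker lists of other cell types (y axis) in 3 comparisons, 1 point per gene and a black bar at the median, with dotted lines at 2-fold. The plasma cell, macrophage, erythroid and basophil medians are 1.91 to 2.48 for TX over nonTX in CD25− (brown) and −0.06 to 0.09 in CD25+ (blue).

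In CD25+ cells the Th17 list was again among those highest after thymectomy. Of its members 11 of 13 were at least 2-fold higher (median 1.91, percentile 100), with Cd163l1, a scavenger receptor of interleukin 17-producing T cells, at 3.65, Il17a at 2.85, Il23r at 2.59 and Il1r1 at 2.55. Type 2 cytokines were higher, with Il13 at 3.39 and Il5 at 2.95 or more, in a Th2 list with 5 of 11 members past 2-fold (median 0.76), although Il4 stood at −0.74. The Tfh list had 3 of 24 members higher and 0 lower (median 0.41, percentile 100), namely Il21 at 2.56, Cebpa at 2.01 and Cxcr5 at 1.24. Ascl2 was at 0.67 and Bcl6 at −0.74. Naive T genes were lower, 6 of 16 by 2-fold or more (median −0.90), with Lef1 at −1.75, Dapl1 at −1.51, S1pr1 at −1.42 and Klf2 at −1.39.

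Cell cycle genes were higher for 13 of 31 members (median 0.98), with Ccnb2 at 1.39 and Tpx2 at 1.40 (0.38 on its other probe), and activated or memory genes for 7 of 20 (median 0.66), with S100a4 at 2.02 and Anxa1 at 1.90. The senescence-associated list had 5 of 11 members higher and 1 lower (median 0.86), with Cdkn2a at 1.86. The Treg list had 4 of 23 higher (median 0.30, percentile 100), with Klrg1, a marker of terminally differentiated cells, at 2.19 and Foxp3 at 0.30. Inhibitory receptors were higher for 2 of 15 (median 0.43), namely Havcr2 at 1.70 and Lag3 at 1.3. The Th1 list stood apart with no member past 2-fold (median 0.52, percentile 100). The pan T and interferon-stimulated lists did not stand apart (medians −0.27 and −0.17).

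Of the lists of other cell types, the plasma cell, macrophage, erythroid, basophil and neutrophil lists did not stand apart (medians −0.06, 0.01, 0.02, 0.09 and −0.33), nor did the NK list (median 0.48, percentile 96.8) or the stromal list (median 0.14). The NK list did so on genes well above background on all 4 arrays (percentile 98.5), with no filter and against unmatched random lists, and the stromal list with normexp (percentile 98.2) and on the held spots alone (median 1.14). B cell genes were higher for 7 of 19 (median 0.62, percentile 99.99), with H2-Aa, an antigen presentation gene, at 1.79 and Cd79a at −0.74. Dendritic cell genes had a median of 0.30 (percentile 98.8, but 97.4 on genes well above background on all 4 arrays and 94.7 on the held spots alone). Platelet genes were lower, with a median of −0.54 (percentile 1.90), but did not stand apart with no filter, with normexp or on the held spots alone (percentiles 2.92, 3.06 and 9.37).

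Over all features, 1173 of 20906 were at least 2-fold higher and 880 lower in CD25+ cells after surgery. Igsf5 led at 16.5-fold, followed by Cd163l1 at 12.5-fold, Tgm2, a transglutaminase, at 11.5-fold, Ccl1 at 11.1-fold, Shroom1 at 11.1-fold, Jcad at 10.9-fold, Lilrb4a at 10.6-fold and Il13 at 10.5-fold. The lowest were Nrp2 at 10.1-fold lower, Lipt1 at 9.62-fold, Alpk3 at 8.64-fold, Tubb2b at 6.23-fold, Adam25 at 5.76-fold, Cybrd1 at 5.46-fold, Dapk1 at 5.29-fold and Tenm1 at 5.24-fold lower. As bounds, G6pc2, Kir3dl1 and Havcr1 were at least 11.5-fold to 13.9-fold higher, and Olfr547, Cadm2 and Myl1 at least 16.9-fold to 30.0-fold lower. Shroom1 and Il13 both lay at −5.37 on nonTX CD25+, near its lowest signal well above background (−5.69). Adam25 and Tenm1 lay at −6.13 and −5.93 on TX CD25+, where it was −6.24. The counts of this comparison rest on the nonTX CD25+ array and on its scaling. Its spike-in controls were brighter than on the other arrays, and scaling on them moved the median of measured log2 ratios from −0.12 to 0.68 here and gave 5504 higher and 215 lower, while normexp on the held spots gave 187 and 244. Spike-in scaling adds 1 constant per array, so it shifts all list medians together and hardly changes their percentiles. It does change the medians, and with them the directions and 2-fold counts of single lists. The platelet median went from −0.54 to 0.26 here.

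The surgery ratios of the 2 fractions share no array. Both fractions of a surgery group may come from the same mice, so their agreement need not be 2 independent observations of surgery. Across 18068 features well above background on all 4 arrays they correlated with a Pearson r of 0.446 and a Spearman rho of 0.453, across genes that are not independent replicates. Of 13377 genes with a symbol measured in both fractions, 463 were at least 2-fold higher in both, where 72.7 would be expected of independent lists, and 108 were lower in both, against 14.5 expected. Opposite directions were seen for 22 genes higher in CD25− and lower in CD25+, against 38.9 expected, and for 31 the other way, against 27 expected. The largest differences toward CD25− were those of Prtn3, a neutrophil protease, with log2 ratios of 1.55 in CD25− and −2.34 in CD25+, Oosp1 (3.10 and −0.69), Tnfrsf17 (3.31 and −0.47), Slpi (4.44 and 0.76) and Insl5 (3.23 and −0.27). Toward CD25+ they were those of Shroom1 (−0.53 and 3.47), Igsf5 (0.23 and 4.05), Ly75, the endocytic receptor DEC-205 (−2.62 and 1.1), Ccdc80 (−2.06 and 1.52) and Calca, the gene of calcitonin and its related peptide (−1.73 and 1.84). None of these differences has a replicate.

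**Figure D4:**
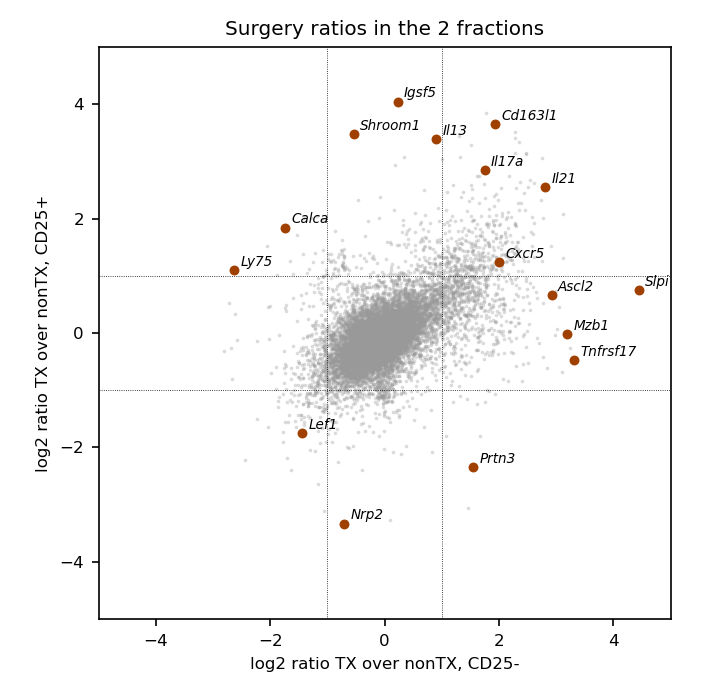
Log2 ratio of TX over nonTX in CD25+ (y axis) against CD25− (x axis) for 12509 genes with a symbol that were well above background on all 4 arrays, 1 point per gene, with dotted lines at 2-fold. Ascl2 lies at 2.92 on the x axis and 0.67 on the y axis, and Il17a at 1.75 and 2.85.

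Between the fractions, regulatory T cell genes set CD25+ apart. Without surgery 21 of 23 Treg list members were at least 2-fold higher in CD25+ than in CD25− cells (median 2.11), and after surgery 18 of 23 (median 1.75). Lrrc32, which encodes the carrier of latent TGF-beta on regulatory T cells, was 21.3-fold higher without surgery and Klrg1 had log2 ratios of 3.01 and 4.25. Th17 genes were higher in CD25+ cells for 8 of 13 and 9 of 13 members (medians 1.1 and 1.44), with Il23r at 2.25 and 3.34. Inhibitory receptors were higher for 8 of 15 and 3 of 15 (medians 1.01 and 0.39), but the first median was 0.084 at percentile 58.8 without shared members and 0.28 at percentile 81.7 with normexp. Naive genes were lower for 3 of 16 and 5 of 16 (medians −0.22 and −0.41, the first not standing apart with normexp, with quantile normalization or against unmatched random lists), with Dapl1 at −3.0 and −3.05. Tfh genes were mixed, with 2 of 24 higher and 3 lower without surgery (median 0.33, percentile 99.4) and 0 higher and 6 lower after it (median −0.20, percentile 0.960). Without surgery the list did not stand apart with normexp (median −0.0022), on the held spots alone or without shared members. Cd40lg, the signal that T cells give to B cells, was at −2.29 and −2.03, and Ascl2 at −0.55 and −2.80. In cell cycle genes 4 and 0 of 31 were higher (medians 0.57 and 0.22). In the activated or memory list 3 and 4 of 20 were (medians 0.39 and 0.31), the first not standing apart with normexp (median 0.21) or on the held spots alone, where the second was −0.24 and did not stand apart either.

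Markers of several other cells were lower in CD25+ than in CD25− cells. Without surgery the basophil median was −2.37, the NK median −1.44, the platelet median −1.39, the dendritic cell median −1.08 and the plasma cell median −0.63, all below the 2.5th percentile. The macrophage median was 0.48 (percentile 99.65, but 94.9 on the held spots alone). The neutrophil median was 0.75 (percentile 98.9), but the list did not stand apart on genes well above background on all 4 arrays (median 0.39), with normexp (median 0.39) or on the held spots alone (median 0.39). The erythroid median was −0.03 (percentile 37.4), but the list stood lower with the mean over probes (median −0.97) and on the held spots alone (median −0.50). The plasma cell list did not stand apart with normexp, with no filter or on the held spots alone. The B cell list did not stand apart (median 0.22, percentile 82.9), but stood higher in CD25+ cells on genes well above background on all 4 arrays (median 0.88). After surgery the basophil, platelet, plasma cell, erythroid, dendritic cell, macrophage and NK medians were −4.99, −3.63, −2.52, −1.83, −1.69, −1.43 and −1.35, and the B cell list did not stand apart (median 0.17), but stood higher on the held spots alone (median 0.64). Each fraction comparison shares an array with each surgery comparison, so their values are not independent. The comparison after surgery shares the TX CD25− array with the surgery comparison of CD25− cells. The comparison without surgery shares the nonTX CD25+ array with that of CD25+ cells.

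Without surgery 1434 of 20625 features were at least 2-fold higher in CD25+ cells and 1138 lower. After surgery the numbers were 1688 and 1323 of 21186. Beyond Lrrc32, Foxp3 and Il2ra, the highest without surgery were Arhgap20 at 15.1-fold, Cx3cl1, a membrane-bound chemokine, at 14.1-fold, Slc7a10 at 13-fold, Slc35d1 at 12.7-fold and Cyp4f18 at 11.4-fold. The lowest were Aqp1 at 20.7-fold lower, Cavin2 at 13.8-fold, Shroom1 at 11.1-fold, Pdlim4 at 10.9-fold, Prss34, a basophil protease, at 9.94-fold, Car1 at 9.85-fold, Pf4 at 9.65-fold and Igfbp4 at 9.30-fold lower. As bounds, Olfr547, Stra6 and Bmp2 were at least 20.9-fold to 27.1-fold higher, and Dmbt1, Aqp9 and Mcpt8 at least 13-fold to 18.6-fold lower. Olfr547 lay at −1.34 on the nonTX CD25+ array and was not well above background on any other array. Shroom1 lay at −5.37 there, against −1.90 on TX CD25+, −1.90 on nonTX CD25− and −2.43 on TX CD25−. Their ratios in this comparison and in the surgery comparison of CD25+ cells both rest on that array. After surgery Cntn1 was 44.4-fold, Bmp2 37.7-fold, Lingo4 21.3-fold and Calca 19.9-fold higher, and Popdc3 and G6pc2 at least 19.3-fold and 17.6-fold. Mcpt8, another basophil protease, was 90.8-fold lower, Prss34 81.6-fold, Gfi1b 63.7-fold, Klf1, an erythroid transcription factor, 60.8-fold and Cavin2 52.3-fold lower, with Aqp1 and Slc38a5 at least 260-fold and 94.7-fold lower. On the TX CD25+ array Mcpt8, Prss34, Gfi1b, Klf1 and Cavin2 lay at −6.15 to −5.74. That is near the lowest signal well above background there (−6.24), so the size of these folds rests on dim signal. With spike-in scaling the counts without surgery were 643 higher and 2791 lower, and with normexp on the held spots 338 and 239.

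The fraction ratios with and without surgery also share no array, and correlated with an r of 0.598 and a rho of 0.507 across the same 18068 features. Of 13395 genes measured in both, 391 were higher in CD25+ cells in both, against 47.3 expected of independent lists, and 241 lower in both, against 26.3.

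The linear model over the 4 arrays called 0 of 20084 features for fraction and 0 for surgery at an adjusted p under 0.05 with limma, and 3691 and 3515 had an unadjusted p below 0.05. The lowest adjusted p was 0.0949 for fraction and 0.172 for surgery. With an intensity trend limma called 299 features for fraction and 0 for surgery. At 1 residual degree of freedom it called 0 features of the simulated arrays for the surgery effect as well.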

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

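The tests of explanations in this part, and the analysis of held spots alone, were chosen after the results they bear on had been seen, whereas normexp, the mean over probes and the absence of a filter were planned. Some results went in opposite directions in the groups compared, each on 1 array per group, and the difference was not tested. Counted over all genes with a symbol, 22 were at least 2-fold higher in CD25− and at least 2-fold lower in CD25+ cells after surgery, and 31 the other way. Among the named genes, Ly75 had log2 ratios of −2.62 in CD25− and 1.1 in CD25+, Ccdc80 −2.06 and 1.52, Calca −1.73 and 1.84, and Prtn3 1.55 and −2.34. The platelet list had medians of 0.87 in CD25− and −0.54 in CD25+ cells after surgery. In CD25+ it did not stand apart with no filter, with normexp or on the held spots alone (percentiles 2.92, 3.06 and 9.37). For CD25+ over CD25− the Tfh median was 0.33 without and −0.20 after surgery, and the macrophage median 0.48 without and −1.43 after surgery. Without surgery the Tfh median was −0.0022 with normexp and −0.059 on the held spots alone, where the macrophage list did not stand apart (percentile 94.9).

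The E1A spike-in controls, which the main analysis did not use, were brighter on the nonTX CD25+ array than on the others after scaling. Averaged over the 6 controls above the floor on all arrays, the difference was 0.80 from TX CD25+, 0.46 from nonTX CD25− and 0.68 from TX CD25− on the log2 scale.

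Markers of plasma cells, basophils, erythroid cells and macrophages were higher on the TX CD25− array than on the nonTX CD25− array (medians 2.35, 2.48, 2.19 and 1.91). No gene of these lists is in another list, and 7 of 10, 2 of 8, 8 of 16 and 16 of 22 of them lay well above background on all 4 arrays. The tables argue against a general rise of dim probes, since the highest median log2 ratio of any of 20 bins of mean expression was −0.031. A rise of tissue-restricted probes stays open: the keratinocyte median was 0.014, but the stromal list stood apart in the main analysis (median 0.57), though not under 3 other settings, and Insl5, Tomt, Oosp1 and Krt17 were among the highest genes. These were 1 test at first, split after the values were seen. Fewer T cells with every other cell type kept in proportion stays open as the whole cause. It would raise all markers alike only where T cells lack them and they lie above the floor. That was not checked, and 6 of 15 neutrophil genes lay well above background on all 4 arrays. The lower quartile of the basophil list (2.30) lay 1.26 above the upper quartile of the neutrophil list (1.03), and above those of the NK, platelet and dendritic cell lists (1.26, 1.20 and 1.64). By the last criterion used these lists moved apart, but the criterion was rewritten several times after the quartiles were seen. An earlier form, which asked all 4 lists to clear the dendritic cell list, left the cause open.

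Carry-over of such cells into the CD25− fraction, which the CD4 sort should remove, stays open. In the pair without surgery 2 of the 4 lists (basophil and plasma cell) stood lower in CD25+ cells. An earlier criterion, also set after the percentiles were known, counted the platelet and dendritic cell lists, which were lower too, and left out the macrophage list, and would have counted in favour. The B cell list was not lower there (median 0.22, or 0.88 at percentile 100 on genes well above background on all 4 arrays). The erythroid list did not stand lower (median −0.03), except with the mean over probes (median −0.97) and on the held spots alone (median −0.50), the macrophage list was higher in CD25+ cells (median 0.48, not standing apart on the held spots alone), and the plasma cell list no longer stood apart with normexp (percentile 4.50), with no filter (percentile 6.27) or on the held spots alone (percentile 2.96). Whether and why the CD25− array after surgery holds more of these cells stays open, since thymectomy, the sort and the array changed together.

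The Tfh list was higher after surgery in both fractions (medians 0.96 and 0.41). In CD25+ cells the highest upper quartile of the plasma cell, erythroid, platelet and macrophage lists was 0.14, below the Tfh median. This argues against these cells as carriers of the whole rise but does not exclude a part. Of 18 macrophage genes measured in CD25+ cells 3 were at least 2-fold higher, and bounds set to no change keep some quartiles small. Basophils remain open there, with a median of 0.093 over 4 measured genes and an upper quartile of 0.79, and so do B cells, with a B cell list median of 0.62 but receptor genes that disagreed (Cd79b 0.62, Cd79a −0.74 and Ms4a1 at least 1.39). In CD25− cells a change in the T cells and carry-over of other cells cannot be told apart for the 0.96, because the CD25− arrays may differ in both. Ascl2, at levels of −3.44, −2.78, −2.90 and 0.03 on the nonTX CD25+, TX CD25+, nonTX CD25− and TX CD25− arrays, and Mzb1, at −1.48, −1.51, −0.18 and 3.02, were both highest on the TX CD25− array.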

How the results depend on the processing

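Analysis of held spots alone and spike-in scaling were chosen after seeing the data. Counts are given as higher and lower for TX over nonTX in CD25−, the same in CD25+, CD25+ over CD25− in nonTX and the same in TX. Normexp gave 968 and 406, 187 and 244, 338 and 239, and 806 and 732; for both comparisons with the nonTX CD25+ array it could use the held spots only, and otherwise the cause was not tested. A 3-fold threshold gave 1009 and 283, 416 and 277, 533 and 484, and 703 and 793, fewer by construction. Held spots alone gave 1128 and 625, 677 and 530, 815 and 674, and 948 and 783, from fewer features. With no filter on dim probes, 2456 were lower in the first comparison, and the others gave 1968 and 2085, 2698 and 1993, and 3003 and 2116, as more features were counted. A filter on all 4 arrays left 506 lower for TX over nonTX in CD25+ and 759 lower for CD25+ over CD25− in TX, from fewer features. Spike-in scaling shifts whole arrays and gave 622 lower in the first comparison, 5504 and 215 in the second and 643 and 2791 in the third. The share of calls that were higher went from 64.7% to 80.2%, from 57.1% to 96.2% and from 55.8% to 18.7%, and the median log2 ratio to 0.10, 0.68, −0.40 and 0.11 in the 4 comparisons. All other counts stayed within 1.5 times.

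The linear model called 48 features for fraction with normexp, 299 with an intensity trend and 1032 with spike-in scaling, which also gave 1655 for surgery; the other settings gave 0. With spike-in scaling the model's variances were pooled to 1 value for all features, and the cause was not tested. The correlation of the surgery ratios was 0.219 with no filter, 0.417 with normexp and 0.434 after quantile normalization, and 0.438 to 0.446 otherwise. The Tfh median for TX over nonTX in CD25− ranged from 0.88 to 1.19 and stood apart in every setting. The number of gene lists standing apart in a comparison, 86 of 124, ranged from 69 to 87.

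Of 1482 list medians under other settings, 1325 kept their direction and side, 76 no longer stood apart and 22 newly did. The sign changed for 23 that stood apart, 14 of them among those 76, and for 54 that did not, 4 of them among those 22. For 6 of the 23 the setting was spike-in scaling and for 1 median scaling, which add 1 constant per array. They move all list medians together and hardly change the percentiles. Otherwise the cause was not tested. The 23 follow. For TX over nonTX in CD25−, held spots alone gave −0.022 for chemokine receptors, 0.0080 for pan T and −0.48 for NK, and pan T was 0.13 after quantile normalization and 0.19 with spike-in scaling. In CD25+, immediate early genes were −0.0033 with median scaling, −0.10 with normexp, −0.15 on held spots alone and −0.10 without shared members. Cytolytic genes were −0.12 with normexp, platelet genes 0.26 with spike-in scaling and heat shock genes −0.016 on held spots alone. For CD25+ over CD25− in nonTX, Tfh was −0.0022 with normexp, −0.059 on held spots alone and −0.13 with spike-in scaling, which also gave −0.070 for activated or memory, −0.10 for immediate early and −0.20 for glycolysis genes. In TX, held spots alone gave −0.011 for Th1, −0.24 for activated or memory, −0.075 for immediate early and 0.43 for stromal genes, and the mean over probes −0.018 for glycolysis. Of 1012 ratios of named genes under other settings, 856 moved by less than the pooled SD between probes, 0 of those at 2-fold or more changed sign, and 7 smaller ones did. The settings differed widely. With normexp 56 ratios moved by more and 26 did not, and with spike-in scaling 58 did and 56 did not. The mean over probes moved 20 and no filter 19. Quantile normalization, median scaling, outlier spots kept and the authors' log2 table moved 0. Dim genes limit the rest, as 701 of the 3035 calls of the first comparison rest on a bound.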

Other observations

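Stress and effector genes outside the T helper lists also differed with surgery. The heat shock and stress list had 5 of 12 members at least 2-fold higher in CD25− cells (median 0.36, percentile 100) and 3 of 12 in CD25+ cells (median 0.24, percentile 99.99, but a median of −0.016 on the held spots alone). Hspa1a, the inducible HSP70, had log2 ratios of 2.46 and 2.14, Hspb1 2.41 and 1.32, and Atf3 1.6 and 1.51. Cytolytic genes were mixed, with 6 of 14 higher and 1 lower in CD25− (median 0.57) and 3 higher and 1 lower in CD25+ (median 0.37, or −0.12 with normexp, and not standing apart with the mean over probes or on the held spots alone). Gzmb, which encodes granzyme B, was at 2.60 and 2.63, Ccl3 at 2.19 and 1.72, and Prf1, which encodes perforin, at −1.31 and −1.05.

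Chemokine receptors were higher for 7 of 17 members in CD25− (median 0.85) and 5 of 16 in CD25+ (median 0.66), with Ccr4 at 1.11 and 1.27 and Ccr8 at 1.07 (0.74 on its other probe) and 1.44. In CD25− the list did not stand apart on the held spots alone (median −0.022). In CD25+ the list did not stand apart with normexp (median 0.0010, percentile 82.9) or without shared members (median 0.30, percentile 90.3). Glycolysis genes stood apart with small medians (0.27 and 0.14), the second not against unmatched random lists, Hk2 being at 1.51 and 1.5. Apoptosis genes did not stand apart (medians −0.10 and −0.15, but the second was 0.24 and stood apart with normexp and on the held spots alone), with Pmaip1 at 1.77 in CD25− and Bbc3 at −1.31 in CD25+. Immediate early genes had a median of 0.01 in CD25+ cells (not standing apart with normexp, without shared members, on the held spots alone or against unmatched random lists), with Fosb at 1.26, and the recent thymic emigrant list −0.24, with Sox4 at −1.56. Housekeeping genes did not stand apart in either fraction (medians −0.15 and −0.18), except in CD25+ after quantile normalization (median 0.19).

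2 hypotheses were tested on gene lists written before the members' values had been seen, with Zbtb16 and Il18rap as exceptions. The first was that interleukin 17-producing gamma-delta T cells may lie behind the higher Il17a and Cd163l1 in CD25+ cells. Of the 7 measured genes of that list, 4 were at least 2-fold higher (median 1.04, percentile 99.95), which is consistent with it. Its highest members, Ltb4r1 at 2.53, Il17re at 2.26 and Serpinb1a at 2.22, are also used by alpha-beta Th17 cells and were higher in CD25− cells too (2.29, 2.32 and 1.92), where the list did not stand apart (percentile 67.9). The other member past 2-fold, which has only a clone name, was at 1.04 in CD25+ and −0.90 in CD25− cells. It is the list median in CD25+ cells, so that median rests on 1 gene. Sox13, a factor of the gamma-delta lineage, was at −0.13 and Actn2 at −0.94 in CD25+ cells. The list does not separate gamma-delta cells from Th17 cells. A CD4 sort would remove most gamma-delta cells. The second was that fewer NKT cells may lie behind lower Klra1 (−1.73) in CD25− cells. The list was higher, with a median of 0.93 at percentile 99.96 over 11 measured genes, although Zbtb16, the factor that NKT cells depend on, was at −2.23. By the bound set beforehand this would have counted against the hypothesis. After the values were seen it was relabelled as undecided, because the list does not follow Zbtb16 in either fraction. In CD25+ cells the list was also higher (median 0.79, percentile 100), with Klrb1f at 2.54, Fcgr3 at 2.38 and Klrb1b at 2.36, while Zbtb16 was at −1.51. The macrophage list did not rise as a whole in CD25+ cells (median 0.01, upper quartile 0.11), but 3 of its 18 measured genes were at least 2-fold higher. Whether macrophages carry part of the rise was not tested. NK cells stay open as carriers in both fractions, with NK list medians of 0.66 in CD25− and 0.48 in CD25+ cells and an upper quartile of 1.47 in the latter.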
